A study of Bos taurus with 8 samples.

How the data were processed

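RNA of bovine blastocysts was compared on 8 2-colour Agilent arrays, 4 with insulin at 0.1 µg/ml (INS0.1) and 4 with insulin at 10 µg/ml (INS10), each against control RNA on the same array. Per the labels' protocols, total RNA was isolated with the PicoPure kit, amplified in 2 rounds with the RiboAmp HS Plus kit and labelled with Cy3 or Cy5 by the Universal Linkage System, which binds guanine bases. Amplification from very small samples and base-dependent labelling can both alter measured ratios. The dyes were swapped on replicates 3 and 4 of each dose, per the labels. Per the file headers, the deposited scanner tables hold the raw median intensity of each spot in both channels, with the median background intensity around it and a mark for spots to be ignored. The scanner software was not given in the sources used here.

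A deposited table of log2 ratios holds the authors' processed values of the same arrays, with their steps not stated. Set against the scanner values, its columns correlated at 0.993 to 0.998 with background-subtracted, loess-normalised log2 ratios of insulin over control, with slopes of 0.911 to 1.13 and column medians of −0.02 to 0.01. Base 2, centring near 0 and the direction were taken from that comparison, while any scaling between arrays stays unknown. These values served as an alternative only.

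Median intensities were background corrected with normexp (offset 50) on all spots and normalised within each array by loess, with control spots and ignored spots at weight 0 and with no step between arrays. Each array had 45212 spots, of which 1418 were controls, and 139 probe spots over all arrays were marked as ignored and left out. A probe was kept if its intensity exceeded the mean plus 2 SD of the 153 negative control spots in at least 4 of the 16 readings, which left 29384 of 43794 probes. Between 44.1% and 58.8% of probes were detected in Cy5 and between 51.6% and 58.7% in Cy3. The SD of the log2 ratios on an array was 0.298 to 0.430. For arrays, precision is limited by their number.

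Gene symbols came from the platform's annotation as supplied, where 21790 probes had 1 symbol, 22004 had none and 0 had several. Of 15229 symbols, 14141 were current in a RefSeq gene table of assembly ARS-UCD2.0 and 1088 were synonyms there. That table was used for names, gene spans and which genes neighbour each other, and no coordinates are given. A single probe stood for each gene, that with the highest mean intensity, and 2816 of the 11718 named genes had more than 1 kept probe.

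Log2 ratios were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with 1 insulin effect per dose and 1 dye effect per probe shared by all 8 arrays. The ratio of insulin over control was taken from the dyes in the labels. Comparisons were each dose against the control, INS10 against INS0.1, and the mean of both doses against the control. Adjusted p-values follow Benjamini and Hochberg, with a threshold of 0.05. The dye effect passed that threshold for 1538 probes. Each replicate number had the same dye orientation at both doses, so none was swapped against itself. The dye term therefore also takes up any difference between the replicates of opposite dye orientation. Dye and such a difference cannot be told apart, and spread of that kind is taken out of the error. Gene lists were tested with camera (preset correlation 0.01) over 25 lists, with an estimated correlation and fry beside it, and the lists of trophectoderm, inner cell mass, hypoblast, cumulus and granulosa cell, oocyte and maternal, and sperm genes served as cell markers. The lists held 780 entries, of which 77 had no probe with that symbol, and 9 genes were in more than 1 list.

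Genes were named by a rule. For each comparison it takes the 10 largest log2 ratios in each direction among genes past the threshold with the same sign on every array. Where fewer than 10 passed, it fills them by the smallest unadjusted p, and these are given as values. It adds up to 4 members of each list by the smallest unadjusted p, and INSR, IGF1R, IGF2R, IRS1, SLC2A1, POU5F1, NANOG and CDX2 wherever measured. For INS10 against INS0.1 the sign rule is that the 4 ratios of 1 dose all exceed the 4 of the other. The design, the lists, this rule and most alternatives were fixed before the data were examined.

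The labels number the replicates of each dose from 1 to 4, and the numbers were checked for pairing across slides. The difference of replicates 1 and 2 at INS0.1 correlated with that at INS10 at 0.261, and the difference of replicates 3 and 4 at 0.223. Log2 ratios of arrays with the same number correlated at 0.239, 0.309, 0.345 and 0.299, against 0.0375 to 0.236 between arrays of other numbers and the same dye orientation on the other slide. Within a slide, where these arrays share the dose and the dye orientation, replicates 1 and 2 correlated at 0.195 and 0.305 and replicates 3 and 4 at 0.417 and 0.366. The ratios alone therefore do not single out the same number. Over the 16 pairs of arrays of opposite dye orientation the correlation was −0.230 to 0.111, so shared dye bias may add to the values above. From the correlated differences the numbers were treated as pairing the arrays, as shared control RNA or a shared position on the slide would, and a fit with the replicate number as a random block was run as an alternative. Its estimated correlation was −0.04, and 0.21 with a dye effect for each slide.

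Each slide held the 4 arrays of 1 dose. The insulin effect is measured within an array, so slide does not enter it, but the difference between doses cannot be separated from the slide. The procedure was tested on simulated data with the observed spread and dye effect of each probe, with 200 of 29283 probes changed. Error was drawn independently for each array and probe. Error shared by arrays of a number was left out, so the figures may be too favourable for both doses averaged. Of 2-fold changes, 73.1% were recovered for INS0.1, 86.6% for INS10 and 94.0% for both doses averaged, and of 1.5-fold changes 14.9%, 16.4% and 59.7%, with 2, 5 and 5 false calls. Each percent came from 1 random draw of 67 changed probes. The single doses had the same design and a median SE of 0.161 each, so their gap does not show a less sensitive low-dose test. Alternatives covered background correction, normalisation within and between arrays, the detection filter, the dye term, eBayes options, array weights, each dose alone, the authors' values, the replicate block, another threshold and removal of each array in turn. Figures were drawn with Python 3.11.15, NumPy 2.4.6 and matplotlib 3.10.9.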

Results

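Gene expression was measured in bovine blastocysts that had developed in vitro from oocytes matured with or without added bovine insulin. The series asks how insulin in the maturation medium bears on the embryos that form. It compares a low dose of 0.1 µg/ml (INS0.1), a high dose of 10 µg/ml (INS10) and a control without insulin. Each of the 8 arrays carried RNA of 1 insulin group and control RNA in opposite dyes. Each dose had 4 arrays, of which 2 carried insulin RNA in Cy5 and 2 in Cy3. The labels give 4 biological replicates per condition, and the number of embryos in each was not given in the sources used here. Median spot intensities ran from 163 to 255 in Cy5 and from 234 to 348 in Cy3, over median backgrounds of 33 to 47 and 31 to 37. Of 43794 bovine probes, 29384 passed the detection filter, and they covered 11718 named genes. The number of arrays limits the precision, with a median SE of 0.16 log2 units for each dose and 0.11 for both doses averaged.

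INS0.1 replicate 1 stood apart from the other arrays, and its values enter every comparison below. For 274 probes that passed the test as higher when the INS10 arrays were fitted alone, the median log2 ratio on INS0.1 replicate 1 was 0.05. The medians of the same probes on the other INS0.1 arrays were 0.80 to 0.97.

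**Figure D1:**
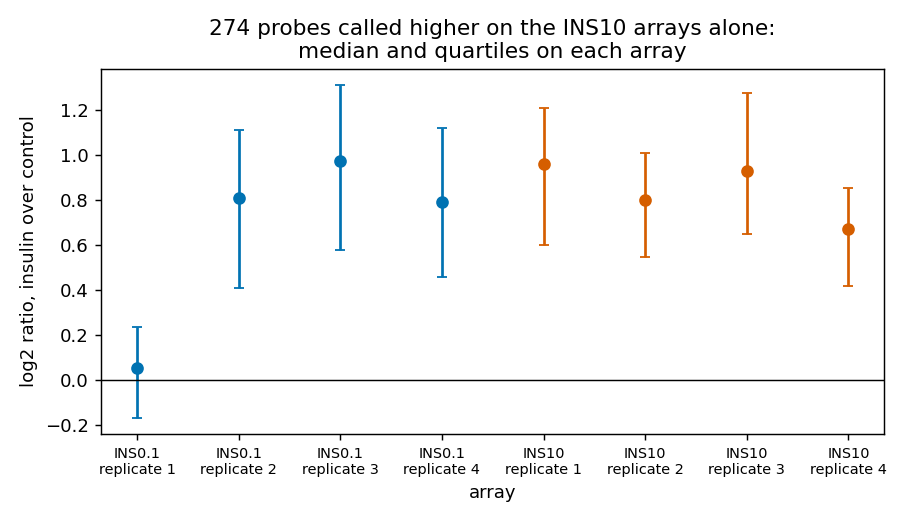
Median log2 ratio of insulin over control (points) and quartiles (bars) on each of the 8 arrays, for the 274 probes that were higher when the INS10 arrays were fitted alone. INS0.1 replicate 1 has a median of 0.05 and quartiles of −0.17 and 0.24, against medians of 0.80 to 0.97 on the other INS0.1 arrays and of 0.67 to 0.96 on the INS10 arrays on which the probes were chosen.

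The first comparison set insulin at either dose against the control, as the mean of both dose effects over 8 arrays. The fit treated these arrays as independent, so error shared by arrays of a number could make its SE and p-values too small. LMNA, which encodes lamins A and C of the nuclear lamina, was 2.47-fold higher with insulin (log2 1.31, SE 0.15, adjusted p = 0.000122). DHCR7, the enzyme of the last step of cholesterol synthesis, was 2.15-fold higher (log2 1.10, SE 0.13, adjusted p = 0.000223). ARPC1B, a subunit of the actin-nucleating Arp2/3 complex, rose 2.12-fold, and CTSZ, a lysosomal cysteine protease, rose 2.09-fold. LOC100125266 (2.31-fold), ARL6IP4 (2.30-fold), the RNA-binding protein gene RALY (2.05-fold), the beta tubulin gene TUBB2C (2.01-fold), the splicing helicase gene DHX38 (1.98-fold) and HN1 (1.97-fold) made up the 10 largest increases among genes higher on 8 of 8 arrays. Other probes of HN1 lay at log2 0.14 and 0.79, of which 1 passed the test. IGF2R, the receptor that clears IGF2 and sorts lysosomal enzymes, rose 1.62-fold (log2 0.70, SE 0.11, adjusted p = 0.00104).

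Fewer genes fell, and by less. SIPA1L2 was 1.51-fold lower (log2 −0.60, SE 0.10, adjusted p = 0.00283), the matricellular protein gene CYR61 was lower at log2 −0.58 (SE 0.11, adjusted p = 0.00539), and ATP6AP2, an accessory protein of the vacuolar proton pump, was 1.48-fold lower (log2 −0.57, adjusted p = 0.00561). MSL3, a chromatin complex subunit, DYNLT3, a dynein light chain, the cap methyltransferase TGS1, the formin DIAPH3, the ribosome biogenesis factor NIP7, IMPAD1 and the chromatin remodelling factor RSF1 fell by 0.45 to 0.53 on the log2 scale, each on 8 of 8 arrays. Other probes of DYNLT3 (log2 0.04) and RSF1 (0.06) and 1 of DIAPH3 (0.00) did not follow, and those of SIPA1L2 (−0.21), NIP7 (−0.22) and IMPAD1 (−0.17 and −0.14) did not pass the test. Each of these 7 genes lost its call on removal of 1 array, with adjusted p reaching 0.0985 for MSL3 without INS10 replicate 2, 0.128 for DIAPH3 without INS0.1 replicate 4, 0.0976 for DYNLT3 without INS10 replicate 1, 0.122 for TGS1 without INS0.1 replicate 3, 0.134 for NIP7 without INS10 replicate 2, 0.1003 for IMPAD1 without INS0.1 replicate 2 and 0.131 for RSF1 without INS10 replicate 3. Without the dye term TGS1, DIAPH3, NIP7, IMPAD1 and RSF1 lost their calls as well (adjusted p = 0.0569 to 0.0726). RSF1 also missed the threshold with the replicate number as a block and a dye effect for each slide (adjusted p = 0.0544). In 8 readings, the 435 probes lowest on 2 arrays of 1 dose were lower on 2 arrays of the other dose with other replicate numbers in 42.4% to 64.8% of cases, none above the 65.1% reached by differences between replicates. For the 49 lowest, as many as were called lower, the median was 46.9%, and 0 readings lay above the 73.5% reached by such differences.

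In all, 484 probes passed the limma test at the adjusted threshold of 0.05, of which 435 were higher (89.9%) and 49 lower with insulin, for 249 and 23 named genes. The median log2 ratio was 0.63 among the higher probes and −0.49 among the lower. Of the 484 probes, 233 had the same sign on every array. At an unadjusted p under 0.05 there were 3030 probes, where chance alone would give 1469.2 if all arrays were independent. Error shared by arrays of a number would raise that figure for the mean of both doses. With the replicate number as a block and a dye effect for each slide there were 2836. The count was 312 without INS0.1 replicate 2, 275 without INS0.1 replicate 3, 290 without INS10 replicate 1, 285 without INS10 replicate 2 and 605 without INS0.1 replicate 1. It was 262 without the dye term and 368 with the replicate number as a block and a dye effect for each slide.

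**Figure D2:**
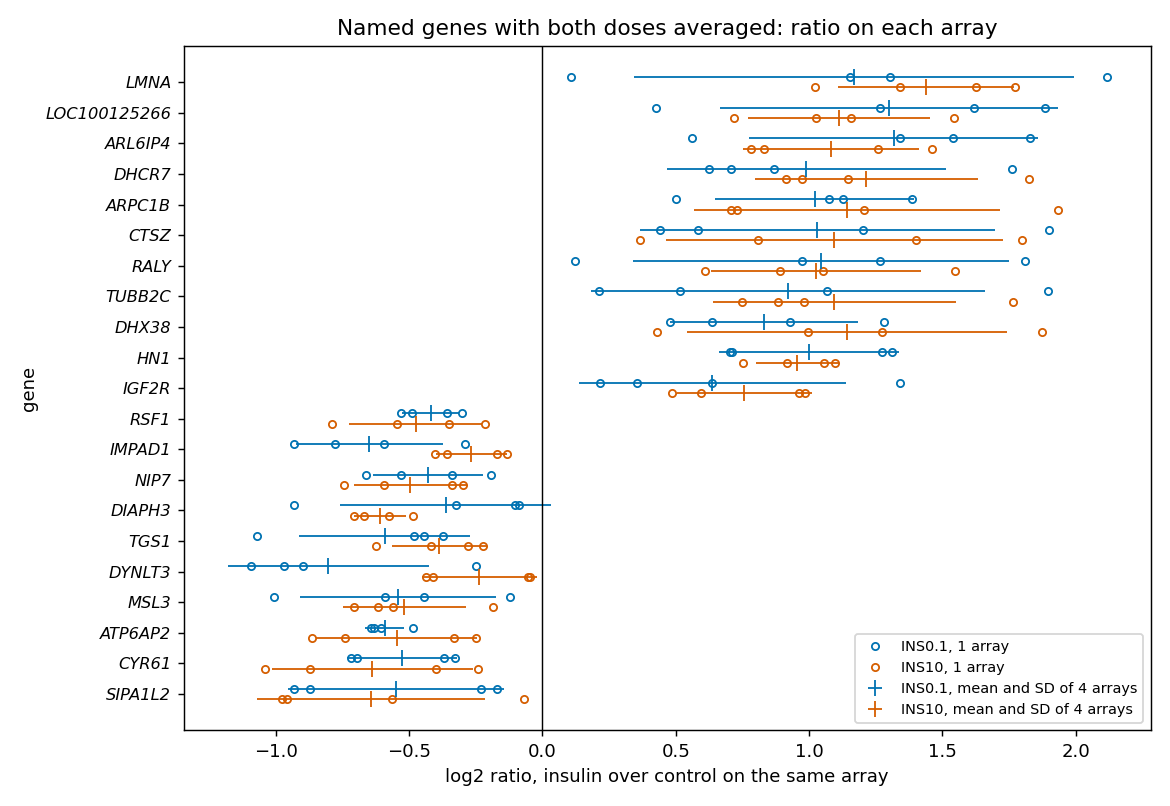
Log2 ratio of insulin over control on each array (circles, 4 per dose) with the mean and SD per dose (line and bar) for the 10 largest increases and the 10 largest decreases among genes with the same sign on every array, and IGF2R, with both doses averaged. LMNA (mean of both doses 1.31) and SIPA1L2 (−0.60) head each direction, and every circle lies on its gene's side of 0.

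Among gene groups fixed before the data were examined, the cytoskeleton list had 6 of 39 measured members higher over all genes tested and 7 adjusted over the list alone. They included the tubulin genes TUBB2C (log2 1.01), TUBB2B (0.82) and TUBB (0.78) and the intermediate filament gene VIM (1.03). Oxidative phosphorylation had 5 of 70 higher, and 5 adjusted over the list alone, among them the ATP synthase subunit gene ATP5D (log2 1.22) and the complex I genes NDUFB7 (0.90), NDUFA10 (0.86) and NDUFS8 (0.73). With eBayes trend and robust options, ATP5D (adjusted p = 0.0871) and VIM (0.0789) missed the threshold. Neither ATP5D nor VIM met the rule of the same sign on every array. Cholesterol synthesis had 2 of 20 higher, DHCR7 and the mevalonate pathway gene MVD (log2 0.83), and 3 adjusted over the list alone, and MVD lost its call without INS0.1 replicate 3 (adjusted p = 0.0581) or INS10 replicate 1 (0.0514). At INS0.1 and INS10 the median of that list was 0.38 and 0.45 on replicate 1, −0.15 and −0.21 on replicate 2, 0.16 and 0.29 on replicate 3, and 0.11 and 0.06 on replicate 4. Error shared by arrays of a number may thus enter it. Insulin and IGF signalling had 1 of 34 higher, IGF2R, and 2 adjusted over the list alone. The insulin receptor gene INSR (log2 −0.04, adjusted p = 0.932) and the glucose transporter gene SLC2A1 (0.07, 0.896) did not pass the test, and IGF1R and IRS1 did not pass the detection filter.

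As whole lists tested with camera at a preset correlation of 0.01, ribosomal proteins lay higher with insulin than other genes (median log2 0.08, 53 of 62 members positive, adjusted p = 0.00849), and so did interferon response genes (median 0.08, 13 of 17 positive, adjusted p = 0.0467). The ribosomal median was 0.16 to 0.24 on the 4 arrays with insulin in Cy5 but 0.02, −0.01, −0.08 and −0.05 on the 4 with insulin in Cy3, and the interferon median ran from −0.09 to 0.37, below 0 on INS0.1 replicate 1 and INS10 replicate 2. Both calls were lost with an estimated correlation, at adjusted p = 0.436 with an estimated correlation for ribosomal proteins and adjusted p = 0.507 with an estimated correlation for interferon response. Of the ribosomal protein genes RPS10 (log2 0.82) and RPL13 (0.65) rose over all genes tested, and 3 did so adjusted over the list alone. No interferon response gene passed limma's test over all genes, 3 passed adjusted over the list alone, and MX1 had the smallest p in that list (log2 0.42, adjusted p = 0.0517). The ribosomal call was lost with ratios centred on the median in place of loess (adjusted p = 0.317), with the authors' values (0.158), with fry (0.0618) and without INS0.1 replicate 3 (0.0745), within a range over the settings tried of 0.00294 to 0.436. The interferon call was lost with the mean of all probes of a gene (0.0688), with the authors' values (0.0868), with fry (0.2002) and without INS0.1 replicate 2 (0.151), INS0.1 replicate 3 (0.0745), INS10 replicate 3 (0.0516) or INS10 replicate 4 (0.168), within a range of 0.00716 to 0.507.

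Markers of the blastocyst lineages changed in few members. Trophectoderm had 2 of 25 markers higher, the transcription factor genes TEAD4 (log2 0.69, SE 0.11, adjusted p = 0.00122) and GATA2 (0.57), and 2 adjusted over the list alone. GATA2 lost its call without INS0.1 replicate 3 (adjusted p = 0.0587), INS0.1 replicate 4 (0.0610), INS10 replicate 1 (0.0578) or INS10 replicate 2 (0.0879). Inner cell mass had 2 of 21 higher and 3 adjusted over the list alone, with the pluripotency factor gene SOX2 at log2 0.69 (SE 0.13, adjusted p = 0.00420). Its other member that passed, the DNA methyltransferase gene DNMT3B (log2 0.51, adjusted p = 0.0317), was positive on 6 of 8 arrays. DNMT3B missed the threshold without INS0.1 replicate 2 (adjusted p = 0.0622), 3 (0.0587) or 4 (0.131), without INS10 replicate 1 (0.103), 2 (0.141) or 4 (0.136), without the dye term (0.308), with median centring (0.0964) or a normexp offset of 16 (0.0857), and with the replicate block and a dye effect for each slide (0.0544). The hypoblast list had 1 of 19 higher, the apolipoprotein gene APOA1 (log2 0.68, adjusted p = 0.244 without the dye term), and 3 higher and 1 lower adjusted over the list alone. Its median was −0.04 while its mean was 0.04 and its test pointed up (adjusted p = 0.770). POU5F1 (log2 0.01, adjusted p = 0.986), NANOG (0.28, 0.516) and CDX2 (0.16, 0.688) did not pass the test.

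Markers of other cells that an embryo sample could hold were measured beside these. Of 15 cumulus and granulosa genes, CYP11A1, the enzyme of the first step of steroid synthesis, rose (log2 0.84, SE 0.15, adjusted p = 0.00346), and 2 rose adjusted over the list alone. The median of that list was −0.04 while its mean was 0.04 and its test pointed up (adjusted p = 0.905). Of 16 oocyte and maternal transcripts none passed limma's test over all genes or over the list alone, and DPPA3 had the smallest p (log2 −0.23, adjusted p = 0.415), with an adjusted p of 0.270 for the list. Of 13 sperm genes PRM1, a protamine that packs sperm DNA, fell (log2 −0.64, SE 0.12, adjusted p = 0.00439), and 2 fell adjusted over the list alone (list adjusted p = 0.212).

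The second comparison asked what the low dose changed against the control on 4 arrays. ARL6IP4 rose 2.49-fold (log2 1.32, SE 0.19, adjusted p = 0.0136), LOC100125266 rose 2.46-fold (1.30, SE 0.19, 0.0136) and LMNA rose 2.25-fold (1.17, SE 0.21, 0.0349). The tetraspanin gene TSPAN17 (2.07-fold), CTSZ (2.04-fold), ARPC1B (2.03-fold), HN1 (1.999-fold, with other probes at log2 0.01 and 0.74 that did not pass), DHCR7 (1.99-fold), FADS2, a fatty acid desaturase (1.92-fold), and GPAA1, which attaches GPI anchors (1.92-fold), followed, each higher on 4 of 4 arrays. No named gene passed limma's test as lower, and the smallest p belonged to DYNLT3 (log2 −0.80, adjusted p = 0.0516, and 0.0388 with the replicate block and a dye effect for each slide) and IMPAD1 (−0.65, 0.0983). IGF2R had a log2 ratio of 0.64 (adjusted p = 0.114).

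At the low dose 32 probes passed, 31 higher and 1 lower, for 17 named genes that rose, and 2258 had an unadjusted p under 0.05. DHCR7 was the only 1 of 20 cholesterol synthesis genes called (1 adjusted over the list alone), FADS2 the only 1 of 25 genes of fatty acid synthesis and lipid storage (1 adjusted over the list alone). Of the 25 lists tested, ribosomal proteins alone passed, with a median log2 of 0.09 and 49 of 62 members positive (adjusted p = 0.0250, and adjusted p = 0.706 with an estimated correlation). None of its members passed limma's test singly over all genes, and 1 did adjusted over the list alone. That list call was lost with ratios centred on the median (adjusted p = 0.554), with the authors' values (0.418), with fry (0.258) and without INS0.1 replicate 1 (0.0609) or replicate 3 (0.290), within a range of 0.0147 to 0.706. With median centring 1 other list passed camera in its place (adjusted p = 0.0353). Interferon response passed camera without INS0.1 replicate 4 (adjusted p = 0.0101).

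The low-dose count was 218 probes without INS0.1 replicate 1, 1 without INS0.1 replicate 4 and 8 without INS10 replicate 2 or INS10 replicate 3. It was 0 by limma without INS0.1 replicate 2 (2052 probes at an unadjusted p under 0.05) or INS0.1 replicate 3 (1811). It was also 0 without the dye term (1534) and with the 4 arrays fitted alone (2505), 9 without background correction, 2 with a normexp offset of 16 and 8 with median centring. It was 58 among probes detected in every reading and 64 with the replicate number as a block and a dye effect for each slide.

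The third comparison asked what the high dose changed against the control on 4 arrays. PRPF6, a component of the spliceosome, rose 2.85-fold (log2 1.51, SE 0.24, adjusted p = 0.0101), LMNA rose 2.71-fold (1.44, SE 0.21, 0.0101) and SEC13, a protein of the COPII coat and the nuclear pore, rose 2.53-fold (1.34, SE 0.24, 0.0132). The SEC13 value came from its brightest probe, and its other probes lay between 0.15 and 0.78. ATP5D rose 2.44-fold (adjusted p = 0.0477, 0.444 with eBayes trend and robust options, 0.0525 without INS0.1 replicate 3, and 0.0509 with the replicate block and a dye effect for each slide), CYP11A1 2.40-fold, DHCR7 2.32-fold, the acid phosphatase gene ACP5 2.28-fold, the kinase gene MAP2K2 2.24-fold, the uridine phosphorylase gene UPP1 2.21-fold and ARPC1B 2.21-fold, each on 4 of 4 arrays. PRM1 was the only named gene that fell, to 1.82-fold lower (log2 −0.87, SE 0.17, adjusted p = 0.0206). IGF2R rose 1.69-fold (log2 0.76, SE 0.15, adjusted p = 0.0310), and PRM1 and IGF2R also lost their calls without INS10 replicate 4 (0.118 and 0.0778).

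At the high dose 128 probes passed, 123 higher and 5 lower, for 68 named genes that rose and 1 that fell, and 1989 had an unadjusted p under 0.05. Cytoskeleton had 3 of 39 higher (5 adjusted over the list alone), namely TUBB2C (log2 1.10), TUBB (0.96) and TUBB2B (0.93). Ribosomal proteins had 2 of 62 higher (3 adjusted over the list alone), RPS10 (1.13) and RPS9 (0.72). Oxidative phosphorylation had 2 of 70 higher (5 adjusted over the list alone), ATP5D and NDUFA10 (0.95). Single members rose in other lists, TEAD4 (0.74) among 25 trophectoderm genes, MCM2 of the replicative helicase (1.11) among 40 cell cycle genes and KEAP1, which restrains NRF2 (0.98), among 28 antioxidant genes, each also 1 adjusted over the list alone. Without INS10 replicate 4 the adjusted p was 0.0588 for TEAD4, 0.0581 for NDUFA10 and 0.131 for RPS9. No list passed camera, and cholesterol synthesis, antioxidants, cytoskeleton, inner cell mass and ribosomal proteins shared the smallest adjusted p of 0.0517. The ribosomal median at this dose was 0.04, and −0.02 with median centring.

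Below the threshold DDX52 (log2 −0.71) had an adjusted p of 0.0503, and 0.0493 with the replicate number as a random block, within a range over the settings tried of 0.0156 to 0.487. With the block and a dye effect for each slide, DDX52 (0.0419), SIPA1L2 (log2 −0.64, 0.0411), CYR61 (−0.64, 0.0435) and the lipase gene PNLIP (−0.73, 0.0301) lay past it. The high-dose count was 0 by limma without INS10 replicate 1 (1447 probes at an unadjusted p under 0.05), replicate 2 (2144) or replicate 3 (1843), 0 without the dye term (1360) and 0 with a normexp offset of 16 (1885). It was 199 without INS0.1 replicate 1 and 297 with the 4 arrays fitted alone.

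The last comparison set the high dose against the low dose. No probe passed limma's test, the smallest adjusted p was 0.9999, and 845 probes had an unadjusted p under 0.05. Chance would give 1469.2 if all arrays were independent, and error shared by arrays of a number would lower that figure for the difference. With the replicate number as a block and a dye effect for each slide, 1985 probes had an unadjusted p under 0.05, and the smallest adjusted p was 0.525. Among the 10 genes of smallest p whose 4 ratios at INS10 all exceeded those at INS0.1, the largest differences were those of the neurotrophin receptor gene NGFR (log2 difference 0.87, SE 0.22, with means of 0.56 at INS10 and −0.31 at INS0.1), PVRL2 (0.73) and ACAD8 (0.69). Among the 10 in the other direction they were those of PRR12 (−0.88), the desaturase gene FADS1 (−0.79, with another probe at 0.39), LOC508858 (−0.79) and INTS2 (−0.78, with other probes at 0.02 and 0.21). No gene list passed, and cell cycle genes had the smallest adjusted p (0.283). The median half-width of the 95% interval was 0.48 log2 units. In simulated data without error shared by arrays of a number, 0 of 67 differences of 1.5-fold, 20.9% of 2-fold and 53.03% of 2.5-fold were recovered. All INS0.1 arrays lay on 1 slide and all INS10 arrays on another, so slide and dose cannot be told apart in this comparison.

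Effects of the 2 doses were also set against each other across probes, which are not independent replicates. Of the 32 probes called at INS0.1, 32 had the same sign at INS10, and 125 of the 128 called at INS10 had the same sign at INS0.1. There were 22 probes higher at both doses, among them those of LMNA, ARL6IP4, DHCR7 and ARPC1B, and 0 lower at both. The correlation of the dose effects was 0.400, but the labels give as many control replicates as arrays per slide, so each control RNA may have been used on both slides. In 100 simulations of unchanged doses with the error shared between slides as observed, the mean correlation was 0.242 and the highest 0.258. In 100 more with the same error correlation, the 32 and 128 probes of smallest p at each dose had the same sign at the other dose in at most 30 and 106 cases and shared at most 7 of the same sign, with 0 called at both. With the error correlation of 0.529 found among the most variable probes, these limits were 32, 125 and 17. The signs alone did not exceed these limits, whereas the overlap of 22 did. The simulations drew the error of each probe independently, so error common to many probes, which would widen the limits, was left out. They therefore cannot settle whether the overlap of 22 or the correlation of 0.400 exceeds shared error. The covariance of the dose effects was 0.0160, against a mean of 0.00741 in the simulations at an error correlation of 0.242. Differences between replicates gave an error covariance of 0.00641, and 0.00961 remained after it was taken off. From 2 arrays per dose the correlation was 0.0959 to 0.213 (covariance 0.00554 to 0.0126) with replicates of different numbers and 0.260 to 0.455 with replicates of the same numbers.

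**Figure D3:**
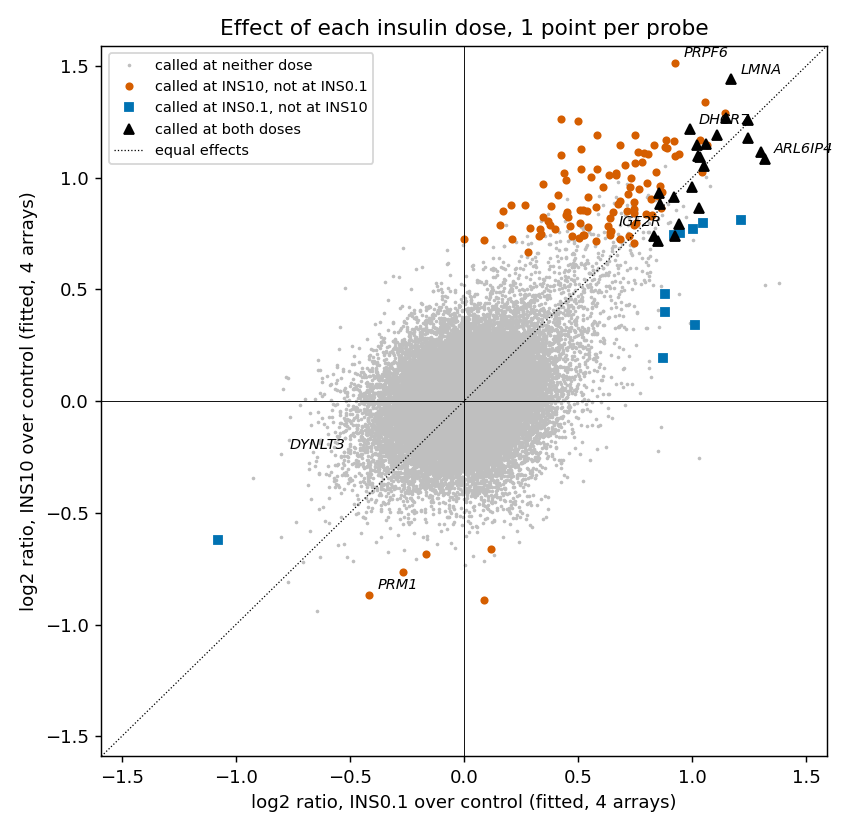
Fitted log2 ratio of insulin over control at INS0.1 (horizontal) and at INS10 (vertical), 1 point per probe, 4 arrays per dose, with probes called at INS0.1, at INS10 or at both marked and a dotted line for equal effects. The correlation across all probes is 0.400, and the 22 probes called at both doses lie in the upper right quadrant.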

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

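The counts of other splits for INS0.1, for INS10 against INS0.1 and for both doses averaged, the tests of loess, of shared control RNA, and of exchanged labels, damped ratios and 1 RNA in both channels on INS0.1 replicate 1 were chosen after the results were seen, whereas the split count for INS10 and the test of gene span and neighbours were set before.

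Most probes called with both doses averaged were higher with insulin, 435 of 484 (89.9%). Loess as the source is argued against, since 82.4% of calls were higher with ratios centred on the median in place of loess. Chance values of control RNA used on both slides are argued against for the highest probes as a group. The 435 probes highest on 2 arrays of 1 dose were higher on 2 arrays of the other dose with other replicate numbers in a median of 81.5% of cases. Of 8 such readings, 7 lay above the highest percent between replicates of 65.1. These probes need not be the 435 that were called. The 435 lowest probes were lower in 42.4% to 64.8% of cases, none above that percent. For the 49 lowest, as many as were called lower, the median was 46.9%, and 0 readings lay above the 73.5% between replicates. For the probes that fell this stays open. A smooth trend with gene span and a shift common to neighbouring genes are argued against as the whole source, since 92.9% of calls were higher after correction for them. The correction takes off only such trends, so a bias that strikes only some short genes stays open. Base composition, which may alter both labelling and amplification, was not tested and stays open beside an effect of insulin.

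INS0.1 replicate 1 showed little of the change on the other arrays, and without it the low-dose count was 218 in place of 32. Exchanged dyes or labels are argued against, because the 274 probes called on the INS10 arrays alone had a median log2 ratio of 0.0547 there, where an exchange would put it as far below 0 as the other INS0.1 arrays lie above it (0.80 to 0.97). Damping of all ratios alike, noise included, is argued against, because the SD of all ratios on the array was 0.884 of the mean of the other INS0.1 arrays. That SD also holds noise and dye effects, so it cannot decide on a loss of the insulin change alone. RNA of 1 group in both channels would give a median near 0, as the 0.0547 is, but a pool of embryos that responded less would give the same, so both may account for it. The 49 probes called lower had a median of −0.31 there with its own values part of the call, while the 53 called lower without this array had −0.11 (quartiles −0.39 and 0.13), against −0.80 to −0.52 on the other INS0.1 arrays, which decides between neither.

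MCM2 was −0.15 on INS0.1 replicate 1 against 1.04 to 1.17 on the other INS0.1 arrays, HSPA1A was −0.25 there against 0.53 to 0.63, and the hypoblast list median was 0.13 there against −0.15 to −0.11. TGS1 was −1.07 on INS0.1 replicate 3 against −0.48 to −0.37. The median of the fatty acid oxidation list was −0.15 on INS0.1 replicate 4 against 0.04 to 0.06. On INS10 arrays, TARS was 0.63 on replicate 4 against 0.11 to 0.19, NDUFB7 was 1.92 on replicate 3 against 0.41 to 0.54, and the SD of all log2 ratios was 0.298 on replicate 2 against 0.404 to 0.425. These 8 values, 3 of them on INS0.1 replicate 1, were singled out by their distance from the other 3 arrays among 216 such groups of 4 arrays, and chance singles out about 1 in 20, or 10.8 here.

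Another 6 genes had ratios of opposite sign at the doses, each on 4 of 4 arrays. The difference of INS10 minus INS0.1 was 0.87 for NGFR, 0.68 for SH3BGRL, 0.52 for DDX3Y, −0.74 for PRPSAP2, −0.77 for FAM107B and −0.63 for APBB3. Other probes differed by −0.21 for SH3BGRL, 0.27 for FAM107B and −0.02 for PRPSAP2. The limma test of the difference in the probes named first gave an adjusted p of 0.9999 for each of the 6 genes.

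Other splits were counted for each comparison. Turning the sign of other arrays gave at most 20 probes at INS0.1 against 32 for the real design, in the split that turns INS0.1 replicate 1, and at most 0 at INS10 against 128. In both, 1 of 8 splits, the real one, reached the real count, and 8 splits are too few for a share under 0.05. For INS10 against INS0.1 the real count was 0, which all 34 of the 34 splits reach by construction (highest other 5), so their number says nothing. With both doses averaged, 1 of the 7 splits that turn both arrays of a number together, the real one, reached the real count of 484. The highest of the other 6 was 15, and 7 splits are too few for a share under 0.05. Of 100 splits drawn from 126 that also turn arrays singly, 1 reached 484 and the highest other was 406, the split that turns INS0.1 replicate 1 alone, but these break the error shared by arrays of a number.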

How the results depend on the processing

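The fits with a dye effect for each slide were chosen after seeing the data, and all other settings before. Of 76 called results for named genes and comparisons, none reversed under any setting, 76 kept their call with the replicate number as a random block, with background subtraction and with array weights, 64 with median centring, 41 with a normexp offset of 16, 35 without the dye term and 36 without INS10 replicate 2. The low-dose count of 32 was 9 without background correction, 2 with offset 16, 8 with median centring, 58 among probes detected in every reading, 0 without the dye term, 0 with the dose alone, 64 with the replicate block and a dye effect per slide and 374 at an unadjusted p under 0.05 with a 1.5-fold change. The high-dose count of 128 was 0 with offset 16, 0 without the dye term, 297 with the dose alone and 394 with the unadjusted threshold and fold. The unadjusted threshold and fold gave 292 for INS10 against INS0.1, and 286 in place of 484 for both doses averaged, which was 262 without the dye term. Removal of 1 array gave 0 to 218 at INS0.1, 0 to 199 at INS10, 0 to 0 for the difference and 275 to 605 for both doses averaged. The cause was not tested, except that fewer arrays or another threshold act by construction. Counts without the dye term cannot show how much of that term is dye. It also holds any difference between the replicates of opposite dye orientation. Detection in every reading kept 13814 probes in place of 29384, by construction.

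Gene lists called at INS0.1 (1 list) numbered 0 with an estimated correlation, 0 with fry, 2 without the filter, 0 with the authors' values and 0 to 3 on removal of 1 array. At INS10 (0 lists) they numbered 7 without the filter and 0 to 4 on removal of 1 array, and for the difference 0 to 0. With both doses averaged (2 lists) they numbered 0 with an estimated correlation, 0 with fry, 1 with the mean of all probes of a gene, 7 without the filter, 1 with median centring, 0 with the authors' values and 0 to 5 on removal of 1 array. The cause was not tested. The random replicate block, with its correlation of −0.04, gave 26, 133 and 538 probes for INS0.1, INS10 and both doses averaged. With a dye effect for each slide and a correlation of 0.21, the block gave 64, 171 and 368. That fit kept 362 of the 484 calls for both doses averaged. The fixed block gave 0 for the difference (limma, 950 at an unadjusted p under 0.05). Among named genes the block changed no call beyond those given with it above. Slide as a block was not run, because each dose had its own slide. Aquantile between arrays left the ratios as they were by construction. Signal over background limits dim genes, since 6612 probes were detected in no reading and CDX2, INSR and the interferon gene MX1 were missed in some.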

Other observations

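The test of gene span and neighbours below was set before its result was seen, while the span and neighbour values that led to it were looked at after the results were known.

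Among metabolic and stress groups not described above, single genes changed with both doses averaged. FADS2, a desaturase of polyunsaturated fatty acids, rose (log2 0.85, SE 0.12, adjusted p = 0.000452, 8 of 8 arrays) as the 1 of 25 genes of fatty acid synthesis and lipid storage over all genes tested and adjusted over the list alone. ACAA1, a peroxisomal thiolase, rose (0.71, SE 0.12, 0.00172, 7 of 8 arrays, adjusted p = 0.0513 without the dye term) as the 1 of 19 genes of fatty acid oxidation by either count. KEAP1, which restrains the antioxidant regulator NRF2, rose (0.89, SE 0.12, 0.000327, 8 of 8 arrays) among 28 antioxidant genes, of which 2 rose adjusted over the list alone. MCM2 rose (0.95, SE 0.15, 0.000958, 7 of 8 arrays) as the 1 of 40 cell cycle genes by either count. The ER chaperone partner gene SDF2L1 rose (0.65, SE 0.13, 0.00900, 7 of 8 arrays) as 1 of 18 ER chaperone genes, of which 1 rose and 1 fell adjusted over the list alone, and lost its call without the dye term (adjusted p = 0.0834), INS0.1 replicate 3 (0.0633), INS10 replicate 1 (0.0531) or INS10 replicate 2 (0.0671). IGF2R was the 1 of 16 imprinted genes by either count, and DNMT3B (adjusted p = 0.0317, 0.308 without the dye term, and 0.0587 to 0.141 without INS0.1 replicate 2, 3 or 4 or INS10 replicate 1, 2 or 4) the 1 of 23 genes of DNA and histone methylation. The inducible chaperone gene HSPA1A rose (0.58, SE 0.12, 0.0115) as 1 of 13 heat shock genes, of which 3 rose adjusted over the list alone, and lost its call without INS0.1 replicate 2 (adjusted p = 0.0546), INS0.1 replicate 3 (0.0609), INS10 replicate 1 (0.0578), INS10 replicate 2 (0.0594) or INS10 replicate 3 (0.0622).

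No gene of glycolysis and glucose transport (23 measured), amino acid and integrated stress response (22), mitochondrial upkeep (21), junctions and fluid transport (22) or p53 and apoptosis (18) passed limma's test over all genes or adjusted over the list alone with both doses averaged. The smallest p in each belonged to PDHA1 (log2 −0.30, adjusted p = 0.389), SLC7A5 (−0.38, 0.113), ESRRA (0.47, 0.101), CLDN4 (0.38, 0.129) and APAF1 (−0.32, 0.226). For mitochondrial upkeep 4 of 21 members were positive, with a median of −0.09 and an adjusted p of 0.117 for the list.

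Genes that rose with both doses averaged had short spans on the chromosome. The median span was 11.9 kb for the 222 of 249 risen genes found in the ARS-UCD2.0 gene table, 24.1 kb for 19 of 23 that fell and 22.5 kb for the rest, and none of 10000 random sets matched on intensity was as short as the risen genes (lowest 15.2 kb). Across genes, which are not independent, the insulin effect correlated with log2 span at −0.133, against −0.01 to 0.12 for differences between replicates. The sign of such a difference depends only on which array is subtracted. In size, the 0.118 of INS0.1 replicates 1 and 2 came near the value of the insulin effect. As INS0.1 replicate 1 showed little of the change, that difference may hold the insulin effect itself with its sign turned. The difference of replicates 3 and 4 gave −0.0134 at INS0.1 and −0.0121 at INS10, and that of INS10 replicates 1 and 2 gave 0.0599. Effects of neighbouring genes correlated at 0.112 over 10730 pairs, where the highest of 1000 random orders was 0.0312 and differences between replicates gave −0.00757 to 0.0520. A bias that follows span and region may contribute to these trends. As the whole source of the rise, a smooth trend with span and a shift common to neighbours are argued against. After correction of each array for both trends, 225 genes were called in place of 272 among 10762 placed genes, 222 of them the same genes. Of the 225, 92.9% were higher, and the median log2 ratio of the risen genes was 0.59 in place of 0.62. With trends this weak the correction could take off little, so a bias that strikes only some short genes would remain and was not tested. Whether the remainder follows base composition was not tested.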
